A study of Mus musculus with 6 samples.

How the data were processed

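Libraries of poly(A) RNA were made from 100 ng of RNA with a SENSE kit, per the labels' protocols, from cells that were dissociated from spinal cord, cleared of myelin on Percoll and selected with CD11b magnetic beads. The deposited values are FPKM per gene, 1 column per library. TopHat2, Cufflinks and Cuffnorm and the genome build GRCm38 are named in the submitters' processing notes. Versions, the annotation, the use of strand and the scaling between libraries are not given in the sources used here. Of 47719 deposited rows, 47219 (98.95%) had an Ensembl ID in GENCODE M21, and 99.94% of these had a deposited locus that overlapped the GENCODE gene on the same chromosome. Positions printed are those of GENCODE M21.

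FPKM divides by length and by library size, so the number of reads is unknown, and no counting interval is given. Low values of genes with 1 annotated transcript were scanned for steps of whole reads, and no step size put more than 34.3% of them within 0.1 of a whole multiple, where chance gives 20% for any 1 step size. An exact 0 can be a failed estimate or a low level: of 56 ribosomal and oxidative phosphorylation genes, 8 were listed at 0 in at least 1 library. All 8 were oxidative phosphorylation genes. Some of them were low in every library (Ndufa1 at most 2.99 FPKM). Others were not: Atp5j2 was listed at 0 in ECS 1 and at 26.7 FPKM in control 3. For genes with an exact 0 each library's value is given, in place of a mean. Cufflinks divides reads between overlapping genes and near-identical copies by estimation, so values of such genes are uncertain.

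Samples were grouped by their labels. FPKM was transformed as log2(FPKM + 1), which understates the change of low genes, and genes with a mean of at least 1 FPKM over the 6 libraries were tested (11315 genes, 23.7%). The test was limma 3.58.1 in R 4.3.3 with a variance trend, ECS minus control, two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. A symbol on several rows was taken from the row with the highest mean. Gene lists were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over 35 lists, and with camera at an estimated correlation and fry beside it. Lists of 25 functions and 14 cell types were fixed, and markers of oligodendrocyte precursors, neurons, ependymal cells and Schwann cells had fewer than 5 tested members. The remaining lists that the report does not describe (oxidative stress, TGF-beta signalling, oxidative phosphorylation, complement and Fc receptors, ion channel genes, T and NK cell, monocyte, oligodendrocyte, erythroid, B cell and astrocyte markers, ribosomal and mitochondrially encoded genes, proliferation, growth factors, cholesterol synthesis and efflux, unfolded protein response, lysosome, anti-inflammatory activation, glycolysis and antigen presentation) had camera adjusted p between 0.253 and 0.892. The median, mean and test direction differed in sign for interferon response, glycolysis, cholesterol synthesis and astrocyte markers.

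The rule for named genes was fixed before the data were examined. It takes the 10 largest changes per direction among genes past the threshold whose groups do not overlap, leaving out predicted gene models. Where fewer pass, genes with the smallest unadjusted p fill up to 5 per direction. It adds up to 4 members of each list described, and Itgam, Cx3cr1, Tmem119, P2ry12, Rara, Tnf, Il1b, Igf1, Apoe, Fkbp5 and Fos. A gene that the rule takes among those with lower values is not reported here.

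The analysis was tested on simulated data with the means and spreads of these libraries. With 200 genes changed there were 3 false calls, and with none changed there were 0 calls. Alternatives fixed in advance were pseudocounts of 0.1 and 0.5, no filter and filters at 0.1 and 5 FPKM, 3 rescalings, a robust variance model, no trend, library weights, a replicate block, each replicate left out, and an adjusted p under 0.1. Figures were drawn with matplotlib 3.10.9.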

Results

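RNA was sequenced from CD11b-positive cells of the spinal cord of Biozzi ABH mice, an inbred strain, after electroconvulsive seizures (ECS), which are seizures induced by a brief electrical stimulus. CD11b is a surface integrin of microglia, the resident macrophages of the central nervous system, and also of other myeloid cells. The mice were 3 months old and had 3 sessions of ECS or control treatment, 1 per day, and were killed on the day after the last session. The control samples are labelled as control and described as naive, while the protocol in the labels speaks of sham treatment. Each group had 3 libraries, and each library came from a pool of 5 mice, so n counts pools and the p-values measure the spread between pools. The deposited values are FPKM (fragments per kilobase of transcript, scaled to the number of fragments in the library) for 47719 genes. Their sum per library ranged from 729831 in control 3 to 1009665 in control 2, and the number of genes above 0 ranged from 11427 in ECS 1 to 14900 in ECS 2. The number of reads behind each library is unknown, because FPKM does not keep it.

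Genes that mark microglia were abundant in both groups and none of those named here passed the test between them. Itgam, which encodes CD11b, was at 584 ± 95.5 FPKM in control and 649.6 ± 87.3 in ECS (SD, n = 3 each). The fractalkine receptor gene Cx3cr1 was at 411 ± 107 and 383 ± 82.7, Tmem119 at 312 ± 79.0 and 295 ± 74.1, and the purinergic receptor gene P2ry12 at 912 ± 149 and 807 ± 266 FPKM in control and ECS (SD, n = 3 each). The lipid carrier gene Apoe was at 576 ± 38.2 FPKM in control and 693 ± 83.6 in ECS, with a log2 fold change of 0.26 ± 0.20 (SE). Transcripts of the immediate early gene Fos and of the cytokine gene Tnf were high in control libraries as well: Fos was at 7616 ± 2130.1 FPKM in control and 7746 ± 2096.9 in ECS, and Tnf at 1139 ± 531 and 1267 ± 312 (SD, n = 3 each).

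The comparison of ECS with control asked which transcripts of these cells differed after the seizures. No gene was called higher and no gene was called lower in ECS among 11315 genes tested with limma on log2(FPKM + 1), at an adjusted p under 0.05. At an unadjusted p under 0.05 there were 194 genes with higher and 220 genes with lower values in ECS, 414 in all, where 566 of 11315 are expected by chance. The values of the 2 groups did not overlap for 847 genes, or 7.49%, and chance alone gives 10% for 3 against 3. The smallest adjusted p was 0.127, for Gm16024, a predicted gene that overlaps Slc35e2 on its own strand and Gm16023 and Gm10563 on the other (GRCm38, chromosome 4, 155616409 to 155616787, plus strand), so that its value is uncertain. It was listed at 0 in all 3 control libraries and at 30.2, 18.2 and 52.8 FPKM in ECS 1, ECS 2 and ECS 3. This gene lies outside the rule for named genes and was chosen after its values were seen.

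The precision set what could be called. The 95% interval of a log2 fold change reached a median of 1.23 to either side, a 2.35-fold difference, and 0.67, a 1.59-fold difference, for the 839 genes with a mean of at least 100 FPKM. In simulated libraries with the spread of these, 0 of 50 genes changed 2-fold, 10 of 50 changed 4-fold, 24 of 50 changed 8-fold and 22 of 50 changed 16-fold were called, and of genes with a mean of at least 100 FPKM, 5, 35, 38 and 47 of 50 were called at those sizes. The changes were made to log2(FPKM + 1), up or down at random, and FPKM below 0 was set to 0. Decreases of low genes were therefore cut short of the size named. The absence of calls does not show that 2-fold changes are absent. Most of the simulated genes with a mean of at least 100 FPKM were called when changed 8-fold or more. However, 200 genes were changed at once there, and the adjustment is less strict when many genes change. These shares therefore do not show what would be called if few genes changed. The simulated genes also varied independently of each other.

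The genes with the smallest unadjusted p are named by rule, and none passed the adjusted threshold. Among those with higher values in ECS were Foxn3, a forkhead transcription factor gene, and Notch4, a Notch receptor gene. Foxn3 was at 37.1 ± 12.6 FPKM in control and 204 ± 78.6 in ECS (SD, n = 3 each), with a log2 fold change of 2.42 ± 0.38 (SE) and a limma adjusted p of 0.690. Notch4 was at 3.66 ± 1.13 and 24.1 ± 6.29 FPKM, with a log2 fold change of 2.43 ± 0.38 (SE) and the same adjusted p. Mxra8, a matrix remodelling gene, was at 3.86 ± 1.55 and 36.1 ± 21.9 FPKM. Cox19, which encodes a factor for assembly of cytochrome c oxidase, was at 1.67, 0.611 and listed at 0 FPKM in control 1, 2 and 3, and at 6.61, 11.6 and 13.1 in ECS 1, 2 and 3. A further row with the symbol Sgsm3 (ENSMUSG00000103565), whose locus overlaps the other Sgsm3 row, was near 0 in 2 control libraries and at 20.0, 11.03 and 14.5 FPKM in ECS 1, 2 and 3, and its assignment between the rows is uncertain.

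Among those with lower values in ECS were Sgsh, a lysosomal sulphatase gene, and Rps15a, a ribosomal protein gene. Sgsh was at 106 ± 18.7 FPKM in control and 44.8 ± 5.21 in ECS (SD, n = 3 each), with a log2 fold change of -1.22 ± 0.25 (SE) and a limma adjusted p of 1.00. Rps15a was at 209 ± 4.75 and 92.1 ± 22.5 FPKM, with a log2 fold change of -1.20 ± 0.25 (SE) and the same adjusted p. Brca1, a DNA repair gene, was at 12.3, 10.5 and 12.9 FPKM in control 1, 2 and 3, and listed at 0, 0.878 and 1.27 in ECS 1, 2 and 3. Tmc4 was at 8.52, 25.7 and 6.0 FPKM in control, and listed at 0 in ECS 1 and ECS 2 and at 0.378 in ECS 3.

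**Figure D1:**
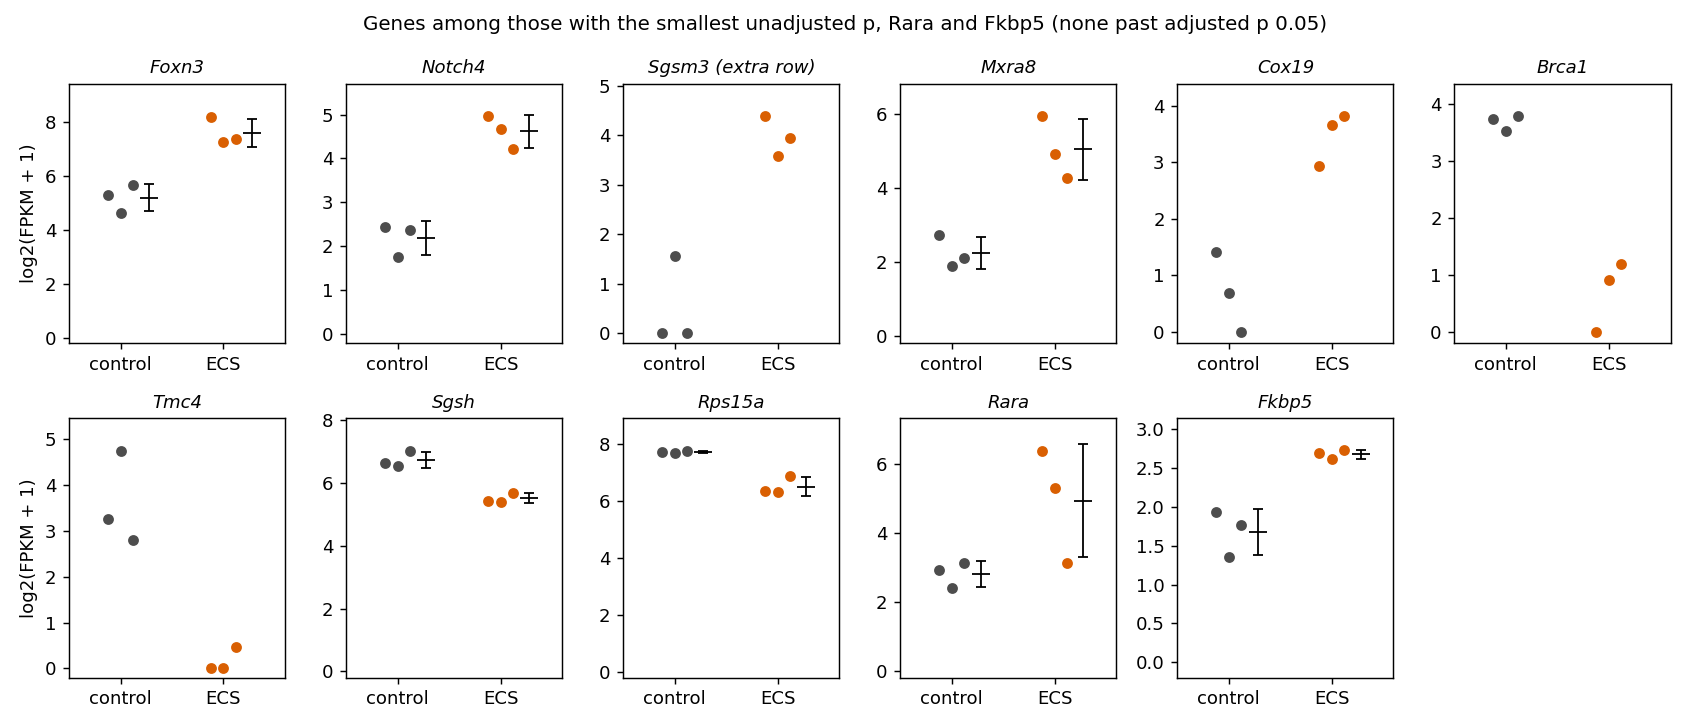
Each panel plots log2(FPKM + 1) of 1 gene in 3 control libraries (grey) and 3 ECS libraries (orange), with the mean ± SD as a black bar where no library is listed at or near 0. The groups did not overlap in any panel, and no gene shown passed the adjusted threshold. All but Rara and Fkbp5 were chosen for a small p, which favours groups that do not overlap. Rara and Fkbp5 had the smallest unadjusted limma p of the genes always named by the rule (0.0277 and 0.0384). Most of the other always-named genes, Itgam and Fos among them, had groups that overlapped, and they are not shown. For Rara the groups nearly met, at 7.78 FPKM in control 3 and 7.85 in ECS 3. Of all genes tested, 7.49% had groups that did not overlap, where chance gives 10%.

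In GRCm38, with positions from GENCODE M21, these genes lie as follows. Foxn3 is on chromosome 12 (99190078 to 99563582, minus strand) and overlaps several noncoding genes. Notch4 is on chromosome 17 (34564268 to 34588503, plus strand), Mxra8 on chromosome 4 (155839680 to 155844088, plus strand) and Cox19 on chromosome 5 (139336189 to 139351418, minus strand). Brca1 is on chromosome 11 (101488764 to 101551955, minus strand), Tmc4 on chromosome 7 (3665790 to 3677553, minus strand) and Rps15a on chromosome 7 (118104372 to 118116188, minus strand). Sgsh is on chromosome 11 (119343425 to 119355536, minus strand). Whether strand was used in counting is not given in the sources used here. Reads of Notch4, Mxra8 and Sgsh therefore cannot be told from those of the antisense genes Gm20462, Mxra8os and Card14 that overlap them. The same holds for Foxn3, with the antisense genes Gm19898 and 3300002A11Rik, and for Tmc4, with Gm15929. Tmc4 also overlaps Leng1 on its own strand. Genes named elsewhere in the report overlap others too, among them Itgam (Gm49368, same strand), P2ry12 (Med12l), Irf9 (Rnf31, same strand), Il1b (Il1bos) and Cx3cr1 (several genes).

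Rara, which encodes a retinoic acid receptor, was at 6.58, 4.30 and 7.78 FPKM in control 1, 2 and 3, and at 82.4, 38.7 and 7.85 in ECS 1, 2 and 3. Its log2 fold change was 2.13 ± 0.78 (SE) with a limma adjusted p of 1.00. Fkbp5, a glucocorticoid-induced co-chaperone gene, was at 2.25 ± 0.638 FPKM in control and 5.41 ± 0.259 in ECS (SD, n = 3 each), with a log2 fold change of 1.00 ± 0.40 (SE), and it did not pass either. The cytokine gene Il1b was at 376 ± 65.0 and 567 ± 214 FPKM, and the growth factor gene Igf1 at 9.44 ± 7.03 and 11.05 ± 2.88.

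Of 39 gene lists fixed before the data were examined, 35 had at least 5 tested members. Neutrophil markers were the only list called: 13 of 15 members had lower values in ECS, with a median log2 fold change of -0.51 and a camera adjusted p of 0.00147. The call was lost with an estimated correlation (adjusted p = 0.916 with an estimated correlation) and with fry (adjusted p = 0.937). No member passed the test over all genes, and 0 passed when adjusted over the list alone. Ltf, which encodes lactoferrin of neutrophil granules, was at 1714 ± 544 FPKM in control and 889 ± 339 in ECS, and Ngp, a neutrophil granule protein gene, at 6764 ± 1231.0 and 4784 ± 1046.9 (SD, n = 3 each). The calprotectin subunit gene S100a9 was at 3302 ± 1792.9 and 1786 ± 259.9 FPKM, and Ly6g at 79.0 ± 32.6 and 42.0 ± 12.4. Without control replicate 2 the list's median was -0.24 and its camera adjusted p 0.0884. The mean log2(FPKM + 1) of the 15 genes was 8.03, 9.04 and 8.69 in control 1, 2 and 3, and 7.89, 8.13 and 8.41 in ECS 1, 2 and 3, and an exact permutation test of these levels gave p = 0.3, where 0.1 is the smallest two-sided p that 3 against 3 can give.

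**Figure D2:**
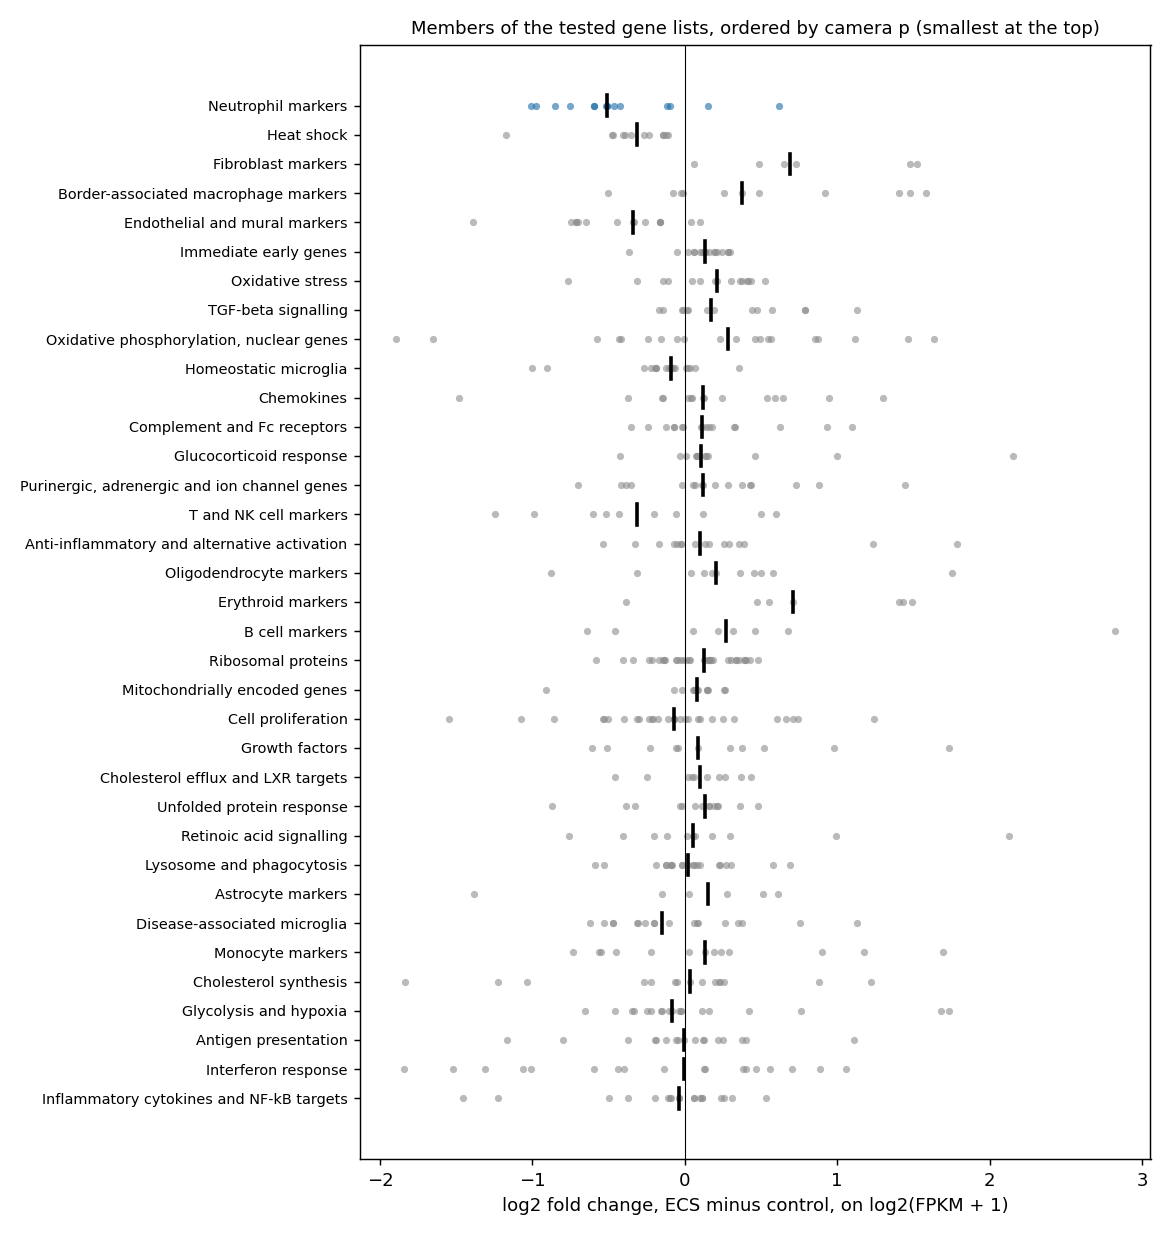
Each grey or blue point is the log2 fold change (ECS minus control) of 1 member of a list, and each black bar is the median of its list. Neutrophil markers, in blue, have a median of -0.51, and the other 34 lists did not pass.

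No list was called higher in ECS. Heat shock genes, which encode chaperones, had lower values for 12 of 12 tested members, with a median of -0.31 and a camera adjusted p of 0.105. Among them Hspa8 was at 1069 ± 126 FPKM in control and 890.1 ± 149 in ECS, and Dnajb1 at 141 ± 35.0 and 100.0 ± 17.9 (SD, n = 3 each). This list passed, downwards, when libraries were rescaled to the same total (adjusted p = 0.0351), with quantile normalization (adjusted p = 0.0160) and with library weights (adjusted p = 0.0222), and with an estimated correlation it passed in none of these 3 (adjusted p = 0.9497, 0.931 and 0.976). Its median was between -0.50 and -0.17 with each replicate left out, and its camera adjusted p was 0.646 without ECS replicate 2. Markers of border-associated macrophages, the macrophages of meninges and vessels, had higher values for 7 of 11 tested members, with a median of 0.38 and a camera adjusted p of 0.195. Cbr2 of this list was at 37.9 ± 24.4 and 93.0 ± 14.4 FPKM, and the lectin gene Clec10a at 41.7 ± 20.4 and 119 ± 81.6. Fibroblast markers had higher values for 6 of 6 tested members (median 0.69, camera adjusted p = 0.131), but these genes were low. Over the 9 genes of that list the mean log2(FPKM + 1) was 0.62, 1.10 and 1.39 in control 1, 2 and 3. In ECS 1, 2 and 3 it was 1.54, 2.37 and 0.83, so ECS 3 lay below control 2 and control 3. Endothelial and mural markers had lower values for 13 of 15 (median -0.34, camera adjusted p = 0.253). These 4 lists had an unadjusted camera p under 0.05, and each had an adjusted p of 0.916 with an estimated correlation. With each replicate left out, the median of border-associated macrophage markers was between 0.15 (without ECS replicate 2) and 0.65 (without ECS replicate 3), and that of endothelial and mural markers between -1.17 (without control replicate 1) and 0.25 (without ECS replicate 3). The median of fibroblast markers was between 0.16 (without control replicate 1) and 1.35 (without ECS replicate 3), and without ECS replicate 2 fewer than 5 members were tested.

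Lists of microglial state did not pass. Homeostatic microglia genes had lower values for 14 of 19 members (median -0.09, camera adjusted p = 0.253), and Fcrls of this list was at 176 ± 33.5 FPKM in control and 93.3 ± 13.1 in ECS (SD, n = 3 each), with a log2 fold change of -0.90 ± 0.25 (SE) and a limma adjusted p of 1.00. Disease-associated microglia genes had 8 of 18 tested members with higher values (median -0.15, camera adjusted p = 0.865). Genes of inflammatory cytokines and NF-kB targets had 9 of 19 with higher values (median -0.04, camera adjusted p = 0.900), and Il6 was at 46.4 ± 7.58 and 24.1 ± 17.1 FPKM. Chemokine genes had 11 of 15 with higher values (median 0.12, camera adjusted p = 0.267), and Ccl24 was at 187, 239 and 213 FPKM in control 1, 2 and 3, and at 1101, 655 and 199 in ECS 1, 2 and 3. Immediate early genes had 17 of 19 with higher values (median 0.13, camera adjusted p = 0.253), glucocorticoid response genes 10 of 12 (median 0.11, camera adjusted p = 0.396) and retinoic acid signalling genes 7 of 11 (median 0.05, camera adjusted p = 0.767). The mean log2(FPKM + 1) of the 19 immediate early genes was 8.81, 8.26 and 8.31 in control 1, 2 and 3. In ECS 1, 2 and 3 it was 8.40, 8.58 and 8.78, so control 1 lay above every ECS library. Interferon response genes had 9 of 18 with higher values (median -0.0031, camera adjusted p = 0.900), among them Irf9, at 12.3 ± 4.23 and 26.8 ± 9.79 FPKM. Among the 9 with lower values, Xaf1 had a log2 fold change of -1.85 ± 1.07 (SE) and Ifi44 of -1.52 ± 0.80 (SE).

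The libraries differed in the markers of other cell types, and these differences cut across the groups. The beta globin gene Hbb-bs was at 156, 30923 and 16524 FPKM in control 1, 2 and 3, and at 34362, 73251 and 619 in ECS 1, 2 and 3. Erythroid markers had a mean log2(FPKM + 1) of 3.77 in control 1, but ECS 3 (5.30) lay above control 3 (5.23) by this measure. The mean includes the alpha globin gene Hba-a1, listed at 0 in 4 libraries, control 3 among them, but not in control 1 or ECS 3. Those zeros may be failed estimates, as described below, so this mean does not settle the order of ECS 3 and control 3. Oligodendrocyte markers had a mean log2(FPKM + 1) of 1.59 in control 1 and 1.68 in ECS 3, and between 2.65 and 3.49 in the other libraries. Endothelial and mural markers were at 1.88 in control 1 and 1.85 in ECS 3, and between 2.81 and 3.94 in the others. Control 1 and ECS 3 were also the pair of libraries with the highest correlation over the tested genes (r = 0.913, across genes, which are not independent replicates), above the 0.875 that was the highest within a group. ECS 1 was the least like the others, with r between 0.779 and 0.817 to each of them. It had 1580 tested genes listed at 0, against 448 to 806 in the other libraries. Rara and Ccl24, described above, had their highest values in ECS 1.

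**Figure D3:**
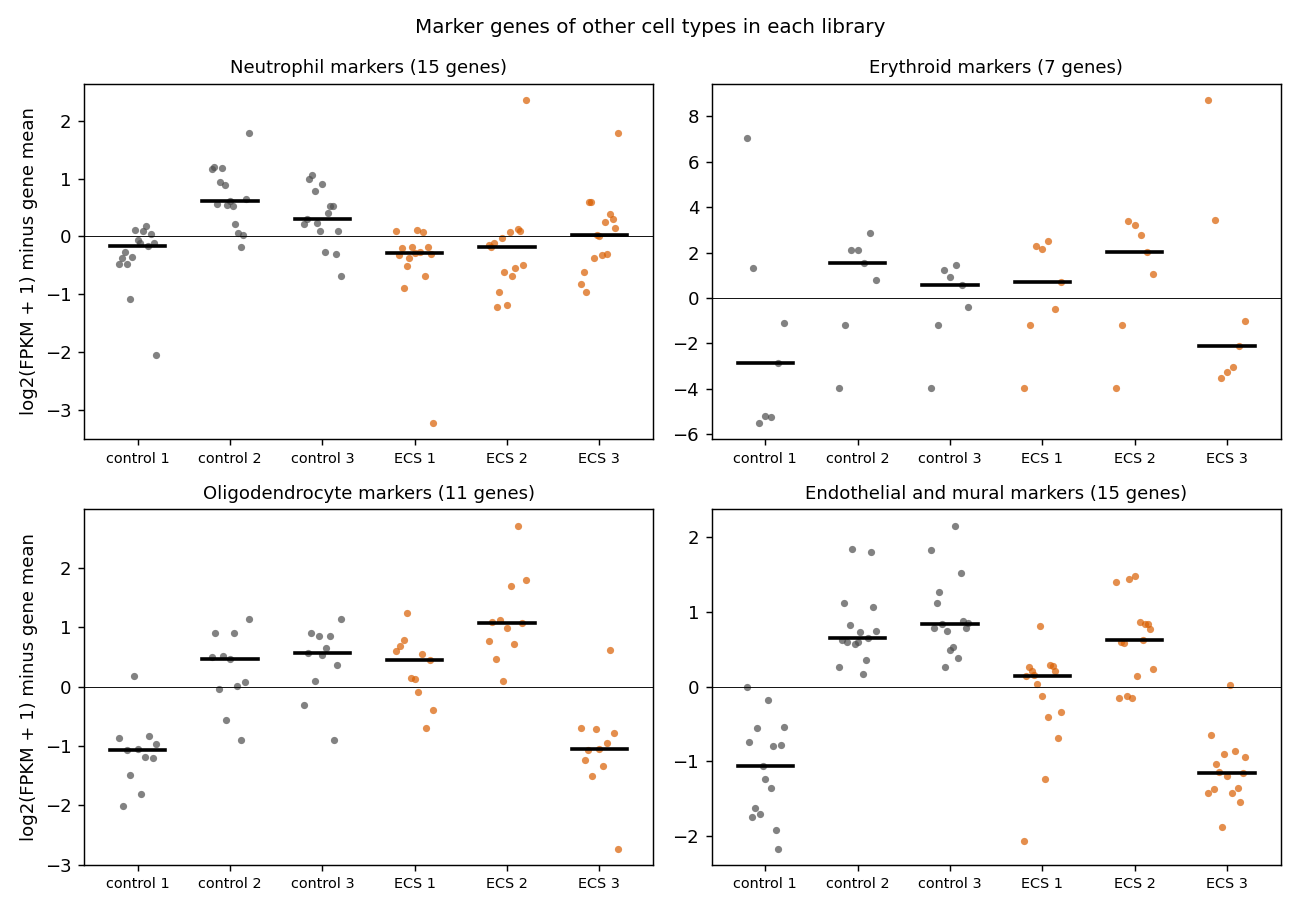
Each point is log2(FPKM + 1) of 1 marker gene in 1 library minus its mean over the 6 libraries (control in grey, ECS in orange), and black bars are medians. Control 1 and ECS 3 have the lowest medians of erythroid, oligodendrocyte and endothelial markers, with Hbb-bs at 156 and 619 FPKM. By mean log2(FPKM + 1), erythroid markers were at 5.30 in ECS 3 and lower, at 5.23, in control 3. That mean includes the alpha globin gene Hba-a1, listed at 0 in control 3 but not in ECS 3, possibly as a failed estimate, so it does not settle their order.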

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

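The covariate Hbb-bs, the removal of genes listed at 0 in any library, the removal of genes where 1 library exceeds the next by over 10 times, the further neutrophil list, the estimated correlation within each alternative, and the covariate with each replicate left out were chosen after the data were seen. The last of these is given for neutrophil markers under the other observations, and is not among the alternatives counted here. The counts of genes higher and lower in ECS were 0 and 0 in limma under every alternative run, and 0 at an adjusted p under 0.1, with between 260 and 557 genes at an unadjusted p under 0.05. Rescaling to the same total moved the median of all genes by -0.08, and the other scalings by less. Replicate numbers are shared by the labels, but libraries with the same number did not deviate together (correlations of deviations from the group means of -0.04, 0.10 and -0.11 for numbers 1, 2 and 3). These values show no pairing, but they cannot exclude that a number marks a shared day or preparation. With a replicate block 0 genes were higher and 0 lower, 0 lists were higher and 1 lower, and neutrophil markers had an adjusted p of 0.00305.

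Neutrophil markers kept their direction in all alternatives run. The median was between -0.59 and -0.24 with each replicate left out, and the call ended without control replicate 2 (adjusted p 0.0884). It also ended with an estimated correlation (median -0.51, adjusted p 0.916) and with fry (-0.51, adjusted p 0.937), and the count of lists lower was then 0 for each. A further neutrophil list had a median of -0.36 and an unadjusted camera p of 0.0785, and a p of 0.442 with an estimated correlation. The adjusted p ranged from 5.56e-06 to 0.937 over the alternatives counted here, and the camera adjusted p was 4.77e-08 with the Hbb-bs covariate and without control replicate 1. The count of lists lower was 2 with libraries rescaled to the same total, quantile normalization, library weights and the Hbb-bs covariate, and the count of lists higher was 1 with that covariate. With each replicate left out, lists higher ranged from 0 to 4 and lists lower from 0 to 3. The calls by alternative given next use the preset correlation: over the alternatives there were 40, and 0 held with an estimated correlation (lowest adjusted p 0.721). Without control 1 immediate early genes passed upwards (adjusted p 0.00162) and endothelial markers downwards (1.61e-05), and the Hbb-bs covariate added both too (0.00638 and 7.12e-06). Without control 2 chemokines (0.0238), oxidative phosphorylation, mitochondrially encoded and ribosomal protein genes passed upwards. Without control 3 heat shock (0.00766) and homeostatic microglia (0.0410) passed downwards, without ECS 1 heat shock (0.0196), and without ECS 2 endothelial markers (0.0298). Without ECS 3 fibroblast (0.00630), border-associated macrophage (0.0301) and oligodendrocyte markers passed upwards, and heat shock (0.0290) and homeostatic microglia (0.0177) downwards. Where a count moved by the replicate left out, fewer samples were fitted; for the others the cause was not tested.

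No list or gene whose direction turned had passed with all libraries at the settings of the report, although homeostatic microglia, chemokines and endothelial markers passed in alternatives given above, and the cause was not tested. Interferon response had a median of 0.0045 with no filter and at 0.1 FPKM, 0.39 at 5 FPKM, 0.025 with quantile normalization and 0.38 without genes at 0. Antigen presentation had 0.013 with no filter and at 0.1 FPKM, and 0.030 at 5 FPKM. Inflammatory genes had 0.011 at 5 FPKM and without genes at 0, 0.014 with library weights, and 0.048 with the Hbb-bs covariate. Retinoic acid signalling had -0.013 with the same total and -0.070 with the covariate, where homeostatic microglia had 0.0040. Fos had -0.067 with the same total and -0.042 with quantile normalization, and with the covariate Cx3cr1 had 0.018 and Tmem119 0.041. With each replicate left out, medians ranged from -0.25 to 0.083 for homeostatic microglia, -0.19 to 0.054 for disease-associated microglia, -0.065 to 0.066 for inflammatory genes, -0.063 to 0.31 for chemokines, -0.19 to 0.069 for interferon response, -0.089 to 0.12 for antigen presentation, -0.13 to 0.23 for glucocorticoid response, -0.17 to 0.25 for retinoic acid signalling and -1.17 to 0.25 for endothelial and mural markers. Log2 fold changes ranged from -0.27 to 0.10 for Cx3cr1, -0.26 to 0.12 for Tmem119, -0.45 to 0.042 for P2ry12, -0.17 to 0.24 for Fos, -0.20 to 0.56 for Tnf and -0.055 to 0.84 for Mt2. Fibroblast markers had fewer than 5 tested members, and no value, at 5 FPKM, without genes at 0 and without ECS replicate 2. Depth is unknown, so its limit on low genes cannot be given.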

Other observations

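Tests of Hbb-bs against the serosal genes, of the serosal genes against treatment, of neutrophil markers with the Hbb-bs covariate at an estimated correlation and with each replicate left out, of alpha globin, and of the splits for counts of genes were chosen only after the result was seen. The further serosal and neutrophil lists were written before their values were seen, and the serosal pattern itself was noticed in the data.

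Of 22 genes known from macrophages of serosal cavities, 16 were highest in ECS 1 and 6 in ECS 2: Alox15 was at 166, 336 and 779 FPKM in control 1, 2 and 3 and at 2255, 647 and 431 in ECS 1, 2 and 3, and Fn1 at 427, 1196 and 1880 and at 5184, 2482 and 868, while Slpi was at 46.4, 262 and 209 and at 672, 1670 and 217. Treatment stays open: 10 of these genes were picked because they showed the pattern, and of the other 12, 11 were tested and 11 had higher values in ECS, with a mean log2(FPKM + 1) of the 12 that was 0.947 higher (exact permutation p = 0.5; 1.16 higher and p = 0.3 over the 22 genes, where 0.1 is the smallest two-sided p that 3 against 3 can give), but over the 22 genes ECS 3 (5.26) lay below control 2 (5.44) and control 3 (6.27). A candidate explanation is that cells of this kind, which CD11b selection would keep, were present in varying amounts: over a further list of these 12 genes, 2 of them also on lists fixed earlier, the median of log2(FPKM + 1) was 2.76 higher in ECS 1 than in control 1, with 12 of 12 higher, but these are the libraries with the highest and lowest level, 8 of the 12 were highest in ECS 1, their mean was 5.32 there, 4.54 in control 3 and 4.48 in ECS 2, and Gata6 reached only 7.70 FPKM in ECS 1. Blood carried along stays open: the level of the 22 genes followed log2(Hbb-bs + 1) over the 6 libraries (Spearman rho = 0.886, exact permutation p = 0.0333; Pearson r = 0.842, exact permutation p = 0.0208; 1 relation tested over 2 sets of genes), but over the 12 further genes alone rho was 0.714 (exact permutation p = 0.136), and r over the 22 genes was 0.204 without the 2 libraries farthest from the Hbb-bs median.

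Lower neutrophil markers in ECS may reflect fewer cells of this lineage, which stays open: a further list of 16 tested lineage genes had a median log2 fold change of -0.36, with 12 lower, and a camera p of 0.0785 (p = 0.442 with an estimated correlation). Whether less blood in the ECS preparations was the whole cause stays open. Hbb-bs was not lower on average in ECS (log2 fold change 1.43 ± 2.39, SE). As a covariate it could therefore not be expected to remove a decrease. With it the list's camera adjusted p was 4.66e-05 and its median -0.52, against -0.51 without it. With each replicate left out, the median with the covariate was between -0.92 (without ECS replicate 3) and -0.351 (without control replicate 2, camera adjusted p 0.0237). Only without control replicate 1 was log2(Hbb-bs + 1) lower in ECS, by 0.962, so that the covariate could have removed the decrease. There the list was still lower at the preset correlation (median -0.661, camera adjusted p 4.77e-08). That lower mean rests on ECS 3, at 9.28, against 14.0 to 16.2 in the other libraries fitted. With an estimated correlation the list was not called with the covariate (p = 0.112, adjusted p = 0.721) or without it (p = 0.109, adjusted p = 0.916). Of the 10 splits of the 6 libraries, the real one included, 9 called at least as many lists as the real one. The real split called 1, and the highest other called 11. With 10 splits a share under 0.05 cannot be reached. The split of control 1, ECS 1 and ECS 2 against the rest gave neutrophil markers an adjusted p of 8.54e-07, smaller than the 0.00147 of the real one, and splits that call several times more lists point to a structure of the libraries other than the groups.

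For the counts of genes, the real split called 0 and the highest other split 3; with a real count of 0, 10 of 10 splits have at least as many by construction, so this tally decides nothing. At an unadjusted p under 0.05 the real split had 414 genes and the highest other 780, and 8 of 10 splits, the real one included, had at least as many as the real one. With 10 splits a share under 0.05 cannot be reached.

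The alpha globin gene Hba-a1 was at 2059 FPKM in control 1 and 6510.4 in ECS 3, and listed at 0 in the other 4 libraries, where Hbb-bs and the erythroid gene Alas2 were highest. The lowest Alas2 value among those 4 was 23.7 times the highest among the other 2, so a failed estimate is a candidate explanation for the zeros. No biological explanation was tested.

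Pax5, a B cell transcription factor gene, was at 652 FPKM in ECS 1 and at most 1.71 in the other libraries. Of the tested genes, 349 had 1 library over 10 times above the next.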
